A study of Mus musculus with 9 samples.

How the data were processed

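Expression was measured on 9 Illumina mouse arrays with biotin-tagged total RNA, 3 per construct, from transduced mouse bone marrow cells after 10 days of culture. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, GenomeStudio 2010.3 was used, and further steps are not given in the sources used here.

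The authors deposited 3 kinds of table. The main table holds an intensity per probe and array on a linear scale, not normalized and without background subtraction as judged from its values, for 45281 probes. Per the file headers, each intensity is followed by a detection p-value, which compares the probe with the array's negative controls. A further table deposited by the authors holds normalized intensity values per array, whose quantiles differ between arrays by at most 0.3 and of which 37.3% to 37.4% lie below 0. They are background-subtracted and quantile normalized as judged from these values, and the rank order within each array equals that of the raw table (Spearman correlation 1). The median of each of the 9 columns is 8. The third table holds the authors' group means, which differ from the mean of the normalized values by at most 0.0667. It allows no test and was used only for that check, and its 3 columns of detection p-values belong to no single sample and were not used.

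The background was corrected with normexp, with the negative controls' mean and variance inferred from the detection p-values, an offset of 16 was added, arrays were quantile normalized and values were taken to log2, all with the neqc function of limma 3.58.1 in R 4.3.3. Probes with a detection p-value under 0.01 on at least 3 of the 9 arrays were kept without regard to group, which left 15870. Probes were named from the platform annotation given with the data: 34885 had 1 gene symbol, 18 had several and 10378 had none. Symbols of 34807 were matched through the Entrez identifier. A gene was represented by its kept probe with the highest mean over the 9 arrays, which gave 9136 genes, 3294 of them with more than 1 kept probe. In MN1-TEL against MN1, of 1481 other probes called along with their gene's probe, 1416 had the same sign. In del DBD against MN1 these numbers were 821 and 802, and in del DBD against MN1-TEL they were 629 and 622. The 2064 kept probes without 1 gene were tested separately. Some symbols belong to families of near-identical genes, such as the kallikreins, chymases and chitinase-like genes, in which a probe may bind several members.

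All 9 arrays entered 1 linear model with the 3 groups as the factor, and the comparisons were MN1-TEL against MN1, del DBD against MN1 and del DBD against MN1-TEL. Two-sided moderated tests of limma were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and with 6 residual degrees of freedom before moderation. A second count took genes that also changed at least 2-fold.

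In all, 29 lists were written before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. They were Hox genes and partners, Stem and progenitor cells, Primary granule, Mature neutrophil, Monocyte and macrophage, Dendritic cell and MHC class II, Mast cell and basophil, Eosinophil, Erythroid, Megakaryocyte and platelet, B lymphoid, T and NK lymphoid, Stroma and endothelium, Polycomb complexes, Cell cycle inhibitors, p53 targets, Proliferation, Myc and ribosome biogenesis, Interferon response, Inflammatory and NF-kB genes, Retinoid pathway, ETS family, Myeloid transcription factors, Cholesterol synthesis, Glycolysis and hypoxia, Unfolded protein and amino acid response, Heat shock and handling stress, Cytokine receptors, and Integrins and adhesion. The 26 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, and again with a correlation estimated for each list. The second form also rests on the 6 residual degrees of freedom, so a call lost there need not reflect correlation. In MN1-TEL against MN1, Hox genes and partners had an estimated correlation of -0.05, below the preset. Their camera adjusted p still went from 0.0059 to 0.0744. Some lists share measured genes, at most 4 for a pair of lists. The Erythroid list names beta globin genes as Hbb-b1 and Hbb-b2, and its measured genes did not include Hbb-bs and Hbb-bt. The named genes were the 8 largest rises and 8 largest falls per comparison among called genes whose groups did not overlap, leaving out unnamed transcripts, up to 4 members per list and comparison with the smallest adjusted p, and Mn1, Etv6, Bmi1, Cdkn2a, Cdkn2b, Hoxa9, Hoxa10, Meis1, Cd34, Kit and Flt3.

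The overlap of the 2 comparisons against MN1 was set beside 100 simulations of unchanged groups against the same MN1 arrays. The steps were tested on simulated data for MN1-TEL against MN1 with 9136 genes. Of genes changed by 0.5, 1 and 2 on the log2 scale, 24 of 68, 52 of 66 and 60 of 66 were recovered with the right sign, and 14 of 150 calls, 9.33%, were unchanged genes. The list moved in the simulation was called, and 0 of 25 unchanged lists were. Simulated genes varied independently, so lists of correlated genes, such as Mast cell and basophil (estimated correlation 0.34), were not tested by it. Far fewer genes were changed in the simulation than the 4995 called in the data.

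Alternatives changed the background correction (none, or normexp with an offset of 50), the normalization (the authors' normalized values floored at 16, median scaling or cyclic loess), the filter (none, all 9 arrays, or all arrays of a group), the probe that represents a gene (the mean of its probes, or every probe), the fit (trend and robust moderation with statmod 1.5.0, the 2 groups alone, array weights, or the replicate number as a block), the threshold (0.01), and the samples, by leaving out each array in turn.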

Results

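The data comprised 9 Illumina mouse BeadChip arrays, which report the brightness of a probe for each transcript in a single colour. Total RNA came from c-kit-enriched bone marrow cells of C57/Bl6 mice that had been transduced with a retrovirus carrying 1 of 3 constructs and kept for 10 days in liquid culture with IL-3 and IL-6 at 10 ng/µl and SCF at 20 ng/µl. MN1 is a transcriptional coactivator that acts with retinoid receptors and transforms mouse bone marrow. MN1-TEL joins MN1 to TEL, an ETS-family transcription factor encoded by Etv6. MN1-TEL del DBD carries a deletion named DBD, the usual abbreviation of DNA-binding domain, and is called del DBD hereafter. Each group held 3 replicates. The labels do not say whether these were separate cultures, so p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision. The series title names independence of MN1 leukemia from Bmi1, a Polycomb gene.

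Mean raw intensity was 667 ± 30.8 in MN1, 943 ± 26.5 in MN1-TEL and 875 ± 20.8 in del DBD (SD, n = 3 each). Between 14249 and 15273 of 45281 probes were detected per array. After normalization, 9136 genes were tested. The groups separated on the first principal component, which held 66.9% of the variance, with MN1 between -58.7 and -56.5, del DBD between 9.85 and 12.8 and MN1-TEL between 44.5 and 48.3. The second component, with 20.1%, set del DBD apart at -34.9 to -28.5. Correlations across genes, which are not independent replicates, were 0.993 to 0.994 within MN1, 0.975 to 0.990 within MN1-TEL, 0.992 to 0.994 within del DBD and 0.878 to 0.954 between groups. The lower values in MN1-TEL belonged to pairs with replicate 2, which the third component, with 6.09%, set apart.

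**Figure D1:**
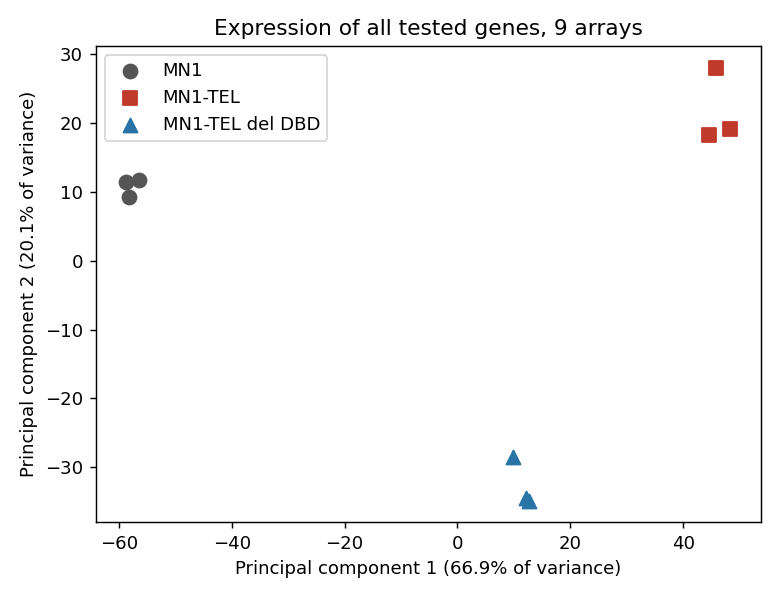
Principal components of 9136 genes, with the first component (66.9% of variance) on the x axis, the second (20.1%) on the y axis and 1 point per array, coloured and shaped by construct. MN1 lies between -58.7 and -56.5 on the first component, MN1-TEL between 44.5 and 48.3, and del DBD between 9.85 and 12.8.

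Differences are given as log2 fold change with its standard error, n = 3 arrays per group, and p-values come from limma adjusted over all 9136 genes unless stated. For a gene not well above background on 1 or more arrays of its dimmer group, the fold is a lower bound, the brighter group's mean against the lowest signal of a detected probe or the gene's own signal, whichever was higher on each array, and is written as at least N-fold. Each fold is that of the probe that represents its gene, so a bound holds for that probe and not for the gene. In a limma fit of every probe, other probes of Ltf and Cd177 gave 5.35 and 5.83 (log2) in MN1-TEL against MN1. Those used gave 9.52 and 8.82. In del DBD against MN1 the other probes gave 3.18 and 4.61, and those used 8.29 and 7.65. Other probes could also give larger changes, as for Asns with -2.14 and -1.85 against -1.62 in MN1-TEL against MN1. For every gene said to have changed, the 3 arrays of the higher group lay above the 3 of the lower, except Bmi1 between MN1-TEL and MN1. Gene lists were tested with camera, a test of whether a list's genes rank higher or lower than the other genes. With an estimated correlation it also has fewer degrees of freedom, so a call lost there need not reflect correlation.

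The constructs themselves were not checked by these arrays. The probe for Mn1 was not detected on any of the 9 arrays, and whether it lies in the transcribed part of the construct is not known. Etv6 measured 8.61 ± 0.03 in MN1, 8.77 ± 0.14 in MN1-TEL and 8.69 ± 0.20 in del DBD (log2, SD, n = 3), with adjusted p = 0.309, 0.667 and 0.668 for the 3 comparisons. With each array scaled to the same median, the first of these, MN1-TEL against MN1, was 0.54 with adjusted p = 0.0113, in a range of 0.0113 to 0.571 over the alternatives.

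The first comparison asked what joining TEL to MN1 changes. Cells with MN1-TEL expressed several neutrophil genes that were at background with MN1. Ltf, the iron-binding protein lactoferrin, was at least 415-fold higher (adjusted p = 8.72e-09), Cd177, a neutrophil surface protein, at least 169-fold (5.65e-09), and Ngp, a granule protein, at least 81.0-fold (6.65e-08). The lysozyme gene Lyz2, in the Monocyte and macrophage list, rose by 7.13 (SE 0.19, adjusted p = 9.28e-09), or 140-fold, at the probe used. Its other probes rose less, by 4.83 and 5.13 in a limma fit of every probe. In the other direction Hpgd, which degrades prostaglandins, was at least 124-fold lower (7.77e-07) and Hoxa9, a homeobox gene tied to leukemic self-renewal, at least 4.80-fold lower (1.90e-06).

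Of the 9136 genes, 4995 changed, 2309 upward and 2686 downward. At least 2-fold changes numbered 1862, with 1007 upward and 855 downward. In 60.8% of genes the groups did not overlap, against 10% by chance. When arrays were scaled to the same median in place of quantile normalization, 3197 rose and 1972 fell, and the median of all genes moved by 0.21, so the split between rises and falls depends on the scaling. The remaining largest rises were Itgb2l, an integrin chain, at least 74.8-fold (2.65e-09), Klk1b11, a kallikrein, at least 49.6-fold (2.34e-09), Ifitm6, an interferon-inducible membrane protein, at least 45.3-fold (5.65e-09), and Mrgpra2b, at least 103-fold (4.92e-08), detected on 2 of 3 MN1 arrays. Klk1b11 and Mrgpra2b belong to families of near-identical genes and are uncertain, and another Mrgpra2b probe, used when detection on all 9 arrays was required, gave -0.18 with adjusted p = 0.470, where the alternatives ranged from 4.21e-11 to 0.470. The remaining largest falls were Tfap2c, a transcription factor of trophoblast and epithelium, at least 87.8-fold (1.25e-06), C2cd4a, at least 59.0-fold (1.43e-07), Cdh3, encoding P-cadherin, at least 48.4-fold (5.65e-09), Bcat1, which transaminates branched-chain amino acids, at least 48.3-fold (7.78e-09), Serpinf1, at least 41.8-fold (7.87e-09), Col4a1, a basement membrane collagen, at least 37.5-fold (1.98e-07), and Mgarp. Mgarp, a mitochondrial protein, was at least 71.5-fold lower (2.58e-07) and was detected on 1 of the 3 MN1-TEL arrays.

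Lists of neutrophil, monocyte, interferon and dendritic cell genes ranked higher than other genes at the preset correlation, and none of these calls held with an estimated correlation. Of 27 measured Mature neutrophil genes, 25 rose and 0 fell, also when adjusted over the list alone, with a median of 3.06, or 2.73 with members below background at their bound (camera adjusted p = 6.86e-15; adjusted p = 0.0744 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, rose by 4.24 (SE 0.11, 8.73e-09). Of 26 Monocyte and macrophage genes, 21 rose and 2 fell, and the counts were the same adjusted over the list alone (median 2.48, adjusted p = 3.82e-09, and adjusted p = 0.0744 with an estimated correlation). Among them the toll-like receptor gene Tlr2 rose by 4.74 (SE 0.11, 7.44e-09) and Csf1r, the M-CSF receptor, was at least 9.23-fold higher (2.65e-07), detected on 1 of 3 MN1 arrays. Interferon response genes numbered 28, with 18 up and 4 down, or 19 and 4 adjusted over the list alone (median 1.24, or 0.96 with bounds; adjusted p = 1.73e-04, and adjusted p = 0.0744 with an estimated correlation). Ifit3 was at least 8.80-fold higher (1.68e-07) and Oasl2 rose by 2.71 (SE 0.11, 1.35e-07). In the Dendritic cell and MHC class II list 6 of 11 rose and 1 fell, 7 and 1 adjusted over the list alone (median 1.09, or 0.58 with bounds; adjusted p = 0.0097, and adjusted p = 0.318 with an estimated correlation). Among genes detected on all 9 arrays this list missed the threshold (adjusted p = 0.690, the highest in a range from 0.0030). The invariant chain gene Cd74 was at least 35.8-fold higher (2.87e-07) and was detected on 1 of 3 MN1 arrays.

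A further 5 lists also ranked higher at the preset correlation but not with an estimated one, and each held genes that fell. In the Cytokine receptors list 12 of 18 rose and 2 fell, with the same counts adjusted over the list alone (median 1.30, or 0.84 with bounds; adjusted p = 6.61e-04, and adjusted p = 0.0744 with an estimated correlation). Csf2ra, a chain of the GM-CSF receptor, rose by 2.17 (SE 0.14, 2.04e-06). Inflammatory and NF-kB genes numbered 25, with 15 up and 4 down, also adjusted over the list alone (median 0.76, adjusted p = 0.0028, and adjusted p = 0.115 with an estimated correlation). The chemokine Ccl6 was at least 25.4-fold higher (1.53e-07), detected on 1 of 3 MN1 arrays. Of 26 Myeloid transcription factors, 13 rose and 3 fell, also adjusted over the list alone (median 0.41, adjusted p = 0.0039, and adjusted p = 0.115 with an estimated correlation). Its strongest members included Egr2, with 4.56 (SE 0.21, 2.62e-07), and Fos, with 3.53 (SE 0.19, 6.18e-07), and 4 of its measured genes are also in the Heat shock and handling stress list. In that list of 16 genes 9 rose and 3 fell, also adjusted over the list alone (median 0.87, adjusted p = 0.0197, and adjusted p = 0.340 with an estimated correlation). Set apart after the values were seen, 8 of its 9 rises were of immediate early genes, which respond within minutes to growth factors and to handling. Of the 9 immediate early genes measured 0 fell. Zfp36 rose by 2.58 (SE 0.11, 1.58e-07), while of 7 heat shock genes 1 rose and 3 fell. This list missed the threshold with median scaling (adjusted p = 0.270) and among genes detected on all 9 arrays (adjusted p = 0.102), in a range of 0.0022 to 0.270. Cholesterol synthesis genes numbered 17, with 10 up and 1 down, also adjusted over the list alone (median 0.58, adjusted p = 0.0125, and adjusted p = 0.126 with an estimated correlation), among them the sterol reductase gene Hsd17b7 with 1.04 (SE 0.13, 1.27e-04).

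The lists of hypoxia, amino acid response and ribosome biogenesis genes ranked lower at the preset correlation but not with an estimated one. Of 20 Glycolysis and hypoxia genes, 0 rose and 18 fell, also adjusted over the list alone (median -1.18, or -1.02 with bounds; adjusted p = 3.81e-07, and adjusted p = 0.0744 with an estimated correlation). Ankrd37, a target of hypoxia-inducible factor, fell by 3.85 (SE 0.21, 6.15e-07), the prolyl hydroxylase gene Egln3 fell by 2.92 (SE 0.16, 6.45e-07) and the glucose transporter gene Slc2a1 by 1.65 (SE 0.11, 2.32e-06). Probes of Egln3 differed, with -2.57 (adjusted p = 3.89e-06) and -0.34 (0.125) at the others in a limma fit of every probe. The Unfolded protein and amino acid response list had 1 of 23 up and 15 down, also adjusted over the list alone (median -0.86, adjusted p = 0.0016, and adjusted p = 0.0811 with an estimated correlation). Trib3 fell by 3.03 (SE 0.20, 2.32e-06) and the asparagine synthetase gene Asns by 1.62 (SE 0.12, 4.75e-06). Myc and ribosome biogenesis genes had 1 of 22 up and 12 down, or 1 and 13 adjusted over the list alone (median -0.41, adjusted p = 0.0404, and adjusted p = 0.410 with an estimated correlation). That call was lost without MN1 replicate 1 (adjusted p = 0.0665), MN1-TEL replicate 1 (0.0651) or MN1-TEL replicate 2 (0.0550) and with array weights (0.0512), in a range of 0.0116 to 0.0665.

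The lists of Hox genes and of stem cell genes ranked lower at the preset correlation but not with an estimated one, and part of their members did not fall. Of 13 Hox genes and partners, 0 rose and 7 fell, also adjusted over the list alone (median -0.55, or -0.43 with bounds; adjusted p = 0.0059, and adjusted p = 0.0744 with an estimated correlation). The Hox partner gene Meis2 was at least 45.5-fold lower (1.28e-06), detected on 2 of 3 MN1-TEL arrays, Hoxa7 fell by 3.11 (SE 0.21, 2.32e-06) and Hoxa11 was at least 2.99-fold lower (5.10e-08). Among genes detected on all 9 arrays the list missed the threshold (adjusted p = 0.340, the highest in a range from 0.0021). Stem and progenitor cells genes had 3 of 19 up and 10 down, also adjusted over the list alone (median -0.77, or -0.62 with bounds; adjusted p = 0.0404, and adjusted p = 0.118 with an estimated correlation). Sox4 fell by 4.58 (SE 0.15, 4.51e-08), Cd34 by 0.94 (SE 0.15, 6.58e-04) and Cd27 was at least 38.3-fold lower (6.89e-08). This call was lost without MN1-TEL replicate 2 (adjusted p = 0.112), with array weights (0.0725) and among genes detected on all 9 arrays (0.110), in a range of 0.0054 to 0.112.

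The other 12 tested lists did not pass the threshold in MN1-TEL against MN1. Of 12 Primary granule genes 4 rose and 4 fell, 4 and 5 adjusted over the list alone, with Mpo, myeloperoxidase, at -3.02 (SE 0.18, 1.24e-06) and Ms4a3 at 2.12 (SE 0.18, 1.02e-05). Its median was -0.18 while its mean was 0.19 (adjusted p = 0.937). Mast cell and basophil genes numbered 23, with 7 up and 4 down, 7 and 3 adjusted over the list alone (adjusted p = 0.410), and in MN1-TEL replicate 2 their median difference from the other MN1-TEL arrays was -0.49 (log2), where the same measure ranged from -0.39 to 0.32 over the 6 arrays of the other groups. The p53 targets had 7 of 16 up and 1 down (adjusted p = 0.0593; 0.0116 to 0.124 over the alternatives) and passed without MN1 replicate 2 (0.0458) or 3 (0.0415) or MN1-TEL replicate 2 (0.0302). The Retinoid pathway had 3 of 5 up and 1 down (0.142), Integrins and adhesion 6 of 17 up and 2 down (0.453), ETS family 5 of 15 up and 5 down (0.937), Erythroid 2 of 10 up and 4 down (0.689), Megakaryocyte and platelet 2 of 14 up and 5 down (0.563), and T and NK lymphoid 1 of 5 up and 4 down (0.260), with the same counts adjusted over the list alone. Proliferation genes, 34 in number, had 4 up and 7 down, also adjusted over the list alone (adjusted p = 0.307). Polycomb complexes had 4 of 28 up and 13 down, 4 and 14 adjusted over the list alone (adjusted p = 0.142). Cell cycle inhibitors had 2 of 8 up and 2 down, also adjusted over the list alone, with a median of 0.14 and a mean of -0.09 (adjusted p = 0.812). Among lists with fewer than 5 measured members, which were not tested, all 3 Eosinophil genes (Ear6, Gata1 and Prg2) rose, 2 of 4 B lymphoid genes rose and Cd79b fell, and in Stroma and endothelium Acta2 rose, Col4a1 fell and the other two, Pdgfrb and Pecam1, were at 0.49 and 0.42. Probes of Acta2 differed, with 2.88 (adjusted p = 7.05e-05) and -0.0024 (0.994) at the others in a limma fit of every probe. Pdgfrb passed without MN1 replicate 1 (adjusted p = 0.0114, the lowest in a range up to 0.544) and Pecam1 without MN1-TEL replicate 2 (0.0089, the lowest in a range up to 0.946).

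Kit, the SCF receptor, rose by 0.73 (SE 0.22, adjusted p = 0.0173), a call lost without MN1 replicate 2 (adjusted p = 0.0599), MN1-TEL replicate 1 (0.0597) or MN1-TEL replicate 3 (0.0564), with median scaling (0.0578) and with the mean of its probes (0.0945), in a range of 3.87e-04 to 0.0945. Cdkn2b, an inhibitor of cyclin-dependent kinases, fell by 2.09 (SE 0.26, 1.41e-04). Bmi1 rose by 0.50 (SE 0.19, adjusted p = 0.0461), with overlapping arrays, and the call was lost in 12 of 24 alternatives, including those that left out any of the arrays except MN1-TEL replicate 2 and del DBD replicate 2. Over the 24 alternatives its adjusted p ranged from 0.0024 to 0.146. Meis1 stood at -0.12 (SE 0.18, 0.596) and Cdkn2a at 0.42 (SE 0.57, 0.563). The probes of Hoxa10 and Flt3 were not detected on any array. The 2-fold count was 1087 without background correction and 1115 among genes detected on all 9 arrays. With 14 lists past the threshold in all, other divisions of these 6 arrays into 3 and 3 gave up to 15 lists by the same test. Those divisions mix both groups on each side and keep part of the real difference.

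**Figure D2:**
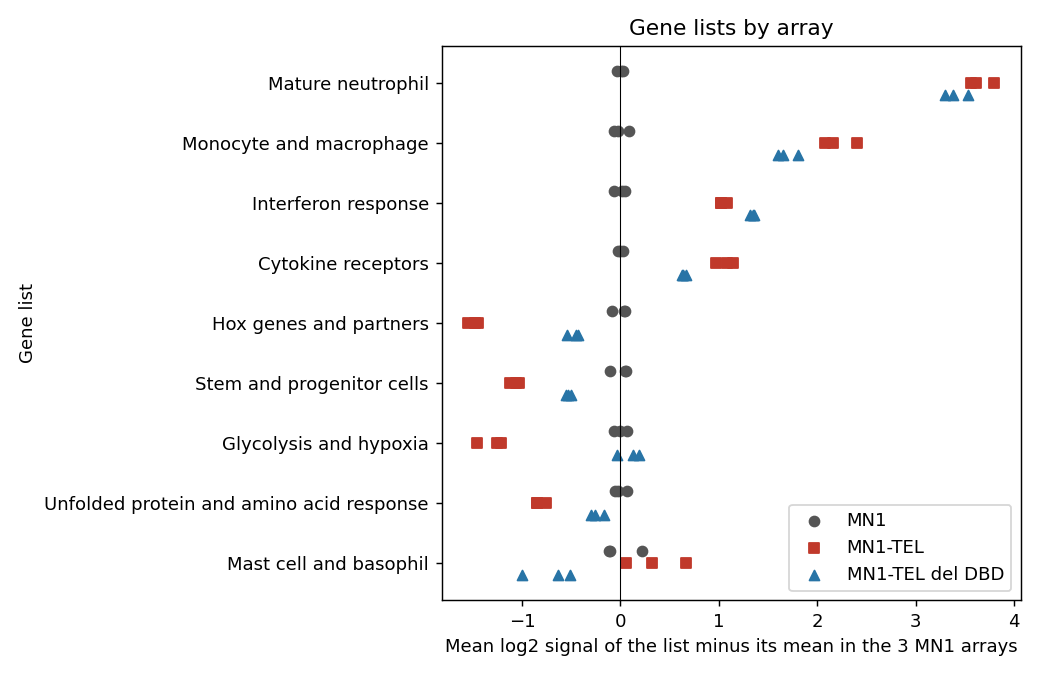
Mean log2 signal of 9 gene lists on each array minus the list's mean over the 3 MN1 arrays, on the x axis, by list on the y axis, with 1 point per array. Mature neutrophil genes lie at 3.56 to 3.80 in MN1-TEL and 3.30 to 3.53 in del DBD, while Glycolysis and hypoxia genes lie at -1.45 to -1.21 in MN1-TEL and between -0.03 and 0.19 in del DBD.

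The second comparison asked how cells with MN1-TEL del DBD differ from cells with MN1. Several neutrophil genes were again high: Ltf was at least 176-fold above MN1 (adjusted p = 3.65e-08), Cd177 at least 75.3-fold (2.26e-08). Lyz2, a gene of the Monocyte and macrophage list, rose by 5.75 (SE 0.19, 6.90e-08). Hoxa9 stood at 0.18 (SE 0.21, 0.544) and Hoxa5 rose by 1.28 (SE 0.20, 9.39e-04), whereas Meis2 was at least 70.8-fold lower (9.62e-07) and Hoxa11 at least 3.10-fold lower (1.06e-07). Kit was lower, with a log2 mean of 12.16 against 13.66 in MN1 (SE of the difference 0.22, 6.57e-04).

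Changed genes numbered 3386, of which 1645 rose and 1741 fell, and 1130 changed at least 2-fold, 676 upward and 454 downward. With only the 2 groups compared in the fit, 4345 genes changed here and 4496 in MN1-TEL against MN1. Of these, 1138 and 1853 changed at least 2-fold. The gap between 3386 and 4995 changed genes thus depends on the shared estimate of the spread. Groups did not overlap in 58.6% of genes, against 10% by chance. With median scaling 2309 rose and 1642 fell, and the median of all genes moved by 0.12. Further large rises were Itgb2l, at least 42.2-fold (7.67e-09), Ngp, at least 40.7-fold (2.57e-07), Mgst1, a glutathione transferase, at least 34.9-fold (4.21e-08), Klk1b11, at least 33.2-fold (5.10e-09), and Chil1, a chitinase-like protein, at least 85.2-fold (9.10e-08), detected on 2 of 3 MN1 arrays. Further large falls were Cdh3, at least 50.1-fold (8.70e-09), Igf2r, the mannose 6-phosphate receptor, at least 27.5-fold (1.43e-07), Glb1l2, at least 21.5-fold (1.19e-06), and Zfp521, a zinc finger gene of early progenitors, at least 16.5-fold (6.29e-07). Tfap2c was at least 78.1-fold lower (3.48e-06), detected on 1 of 3 del DBD arrays, Hpgd at least 83.7-fold lower (5.52e-06), on 2 of 3, and the glutamate receptor gene Gria2 at least 30.5-fold lower (1.96e-07), on 1 of 3.

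In this comparison 7 lists ranked higher at the preset correlation, 2 of them also with an estimated one. In the Mature neutrophil list 24 of 27 rose and 0 fell, 25 and 0 adjusted over the list alone (median 3.00, or 2.47 with bounds), and this call held under both tests (adjusted p = 2.70e-20; adjusted p = 0.0222 with an estimated correlation). S100a8 rose by 4.26 (SE 0.11, 2.26e-08). The Interferon response list had 24 of 28 up and 0 down, 25 and 0 adjusted over the list alone (median 1.21, or 1.16 with bounds), and it too held under both tests (adjusted p = 6.98e-13; adjusted p = 0.0222 with an estimated correlation). Oasl2 rose by 3.22 (SE 0.11, 9.12e-08) and Parp14 by 2.15 (SE 0.14, 3.91e-06). Monocyte and macrophage genes had 20 of 26 up and 2 down, also adjusted over the list alone (median 1.84, adjusted p = 3.47e-10, and adjusted p = 0.0843 with an estimated correlation), with Tlr2 at 3.26 (SE 0.11, 8.76e-08). Dendritic cell and MHC class II genes had 9 of 11 up and 1 down, also adjusted over the list alone (median 1.15, or 0.85 with bounds; adjusted p = 7.59e-04, and adjusted p = 0.274 with an estimated correlation), and missed the threshold among genes detected on all 9 arrays (adjusted p = 0.246, the highest in a range from 6.3e-05). The Inflammatory and NF-kB list had 15 of 25 up and 4 down, also adjusted over the list alone (median 0.81, adjusted p = 0.0021, and adjusted p = 0.183 with an estimated correlation). Cytokine receptors had 8 of 18 up and 2 down, 9 and 2 adjusted over the list alone (median 0.48, or 0.35 with bounds; adjusted p = 0.0047, and adjusted p = 0.0843 with an estimated correlation). Myeloid transcription factors had 12 of 26 up and 5 down, also adjusted over the list alone (median 0.46, or 0.34 with bounds; adjusted p = 0.0325, and adjusted p = 0.274 with an estimated correlation), a call lost without del DBD replicate 3 (adjusted p = 0.0615), with median scaling (0.203) and among genes detected on all 9 arrays (0.0660), in a range of 0.0020 to 0.203.

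Lower lists were Myc and ribosome biogenesis and Mast cell and basophil. The former had 0 of 22 up and 13 down, also adjusted over the list alone (median -0.46, or -0.45 with bounds; adjusted p = 0.0021, and adjusted p = 0.346 with an estimated correlation), with the ribosome biogenesis gene Ftsj3 at -0.93 (SE 0.13, 5.40e-04). The latter had 2 of 23 up and 11 down, also adjusted over the list alone (median -0.80, or -0.70 with bounds; adjusted p = 0.0061, and adjusted p = 0.570 with an estimated correlation), with the IgE receptor gene Fcer1a at -2.73 (SE 0.53, 0.0034). Glycolysis and hypoxia genes had 3 of 20 up and 1 down (median 0.09, adjusted p = 0.557) and Hox genes and partners 3 of 13 up and 2 down (adjusted p = 0.939), both with the same counts adjusted over the list alone. Hox genes had a median of 0.15 but a mean of -0.48, T and NK lymphoid genes a median of -0.31 but a mean of 0.03, and Retinoid pathway genes a median of -0.22 but a mean of 0.65. Primary granule genes had 7 of 12 up and 1 down, also adjusted over the list alone (adjusted p = 0.0578), with the elastase gene Elane at 2.03 (SE 0.22, 1.04e-04). This list passed without MN1 replicate 1 (0.0496) or 2 (0.0334), in a range of 0.0231 to 0.514. The Stem and progenitor cells list, with a median of -0.70 (adjusted p = 0.0531), passed in 10 alternatives, with a range of 0.0109 to 0.0707. Among these were those without MN1 replicate 1 (0.0359), 2 (0.0251) or 3 (0.0471) or del DBD replicate 3 (0.0377), and that with the replicate number as a block (0.0359). Cd34 fell by 0.61 (SE 0.15, 0.0127), a call lost without MN1 replicate 2 (adjusted p = 0.0528) or del DBD replicate 2 (0.0501), in a range of 0.0017 to 0.0528. Bmi1 stood at -0.48 (SE 0.19, 0.0751) and passed without MN1-TEL replicate 2 (0.0142, the lowest in a range up to 0.619). Cdkn2b stood at -0.60 (SE 0.26, 0.101) and passed without MN1-TEL replicate 2 (0.0453) or 3 (0.0252), in a range of 0.0162 to 0.299. Meis1 stood at 0.47 (SE 0.18, 0.0757) and passed without MN1 replicate 3 (0.0210, the lowest in a range up to 0.296). Another Meis1 probe, in a limma fit of every probe, rose by 1.48 (adjusted p = 0.0257). The 2-fold count was 606 without background correction and 572 among genes detected on all 9 arrays. Beside the 9 lists past the threshold, other divisions of the 6 arrays, which mix both groups on each side, gave up to 10.

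The 2 comparisons against MN1 overlapped. In both, 1289 genes rose and 1336 fell, while 109 changed in opposite directions. With median scaling 1898 rose and 1218 fell in both, so this split too depends on the scaling. Independent lists of these sizes would share 416 upward and 512 downward genes, and unchanged groups simulated against the same MN1 arrays shared a mean of 0.02 calls. Unchanged groups give almost no calls, so that mean does not gauge how far the shared MN1 arrays raise the overlap. Fold changes correlated across genes with r = 0.787, against 0.501 in the simulations. Unchanged groups that share a control give a correlation near 0.501 whatever their spread. That value thus does not gauge how much of r = 0.787 comes from the shared arrays. The covariance of the fold changes was 0.738 against 0.0204 in the simulations, a difference of 0.718. The 3 MN1 arrays could not be divided into parts of 2 arrays each. The part of the covariance that comes from shared controls was thus gauged by simulation alone. Among genes that changed in the same direction in both, the difference between MN1-TEL and del DBD did not pass the threshold for 1743. For 394 of the shared rises MN1-TEL lay above del DBD and for 88 below, and for 361 of the shared falls MN1-TEL lay below del DBD and for 39 above.

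**Figure D3:**
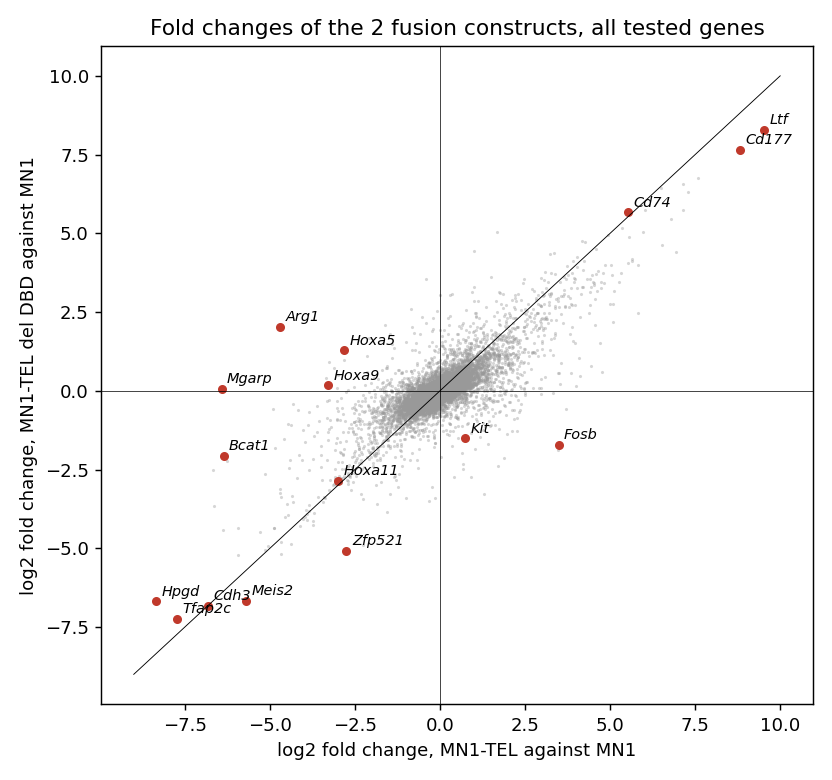
Log2 fold change of each of 9136 genes in MN1-TEL against MN1 (x axis) and in del DBD against MN1 (y axis), with named genes in red and the line of equal change. Ltf and Cd177 lie far up on both axes, while Arg1, Hoxa5 and Fosb lie on opposite sides of 0 in the 2 comparisons.

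The third comparison asked what the deletion changes within MN1-TEL. In cells with del DBD, Hoxa5 was at least 16.9-fold higher (adjusted p = 3.59e-06), detected on 2 of 3 MN1-TEL arrays, Hoxa7 rose by 3.83 (SE 0.21, 5.47e-06), and Hoxa9 was at least 5.44-fold higher (9.29e-06). Arg1, arginase, was at least 51.5-fold higher (3.15e-06). The immediate early gene Fosb was at least 25.6-fold lower (8.05e-06), the fractalkine receptor gene Cx3cr1 fell by 4.28 (SE 0.31, 2.22e-05), and Kit fell by 2.23 (SE 0.22, 9.94e-05). Bmi1 fell by 0.98 (SE 0.19, 0.0043), with adjusted p between 3.98e-04 and 0.0208 over the alternatives.

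Changed genes numbered 2689, with 1373 up and 1316 down, and 847 changed at least 2-fold, 412 upward and 435 downward. The groups did not overlap in 41.9% of genes, against 10% by chance. With median scaling 1001 rose and 1564 fell. Further large rises were Mgarp, at least 74.8-fold (3.15e-06), Cox6a2, a cytochrome oxidase subunit, at least 12.5-fold (5.23e-05), both detected on 1 of 3 MN1-TEL arrays, Stc2, stanniocalcin, at least 19.6-fold (2.59e-06), detected on 2 of 3, Bcat1, at least 11.6-fold (1.52e-06), Hif3a, a hypoxia-inducible factor subunit, at least 11.6-fold (3.78e-06), and C2cd4a, at least 10.3-fold (1.43e-05). Further large falls were Aldh3a1, an aldehyde dehydrogenase, at least 26.1-fold (5.62e-06), B4galnt2, a glycosyltransferase, at least 6.62-fold (6.68e-06), Hs6st2, a heparan sulfate sulfotransferase, with -4.54 (SE 0.28, 8.62e-06), Lhfp, with -4.16 (SE 0.28, 1.43e-05), and the mast cell chymase genes Cma2, with -4.10 (SE 0.48, 2.89e-04), and Mcpt4, with -4.01 (SE 0.53, 5.41e-04). Chymase genes are similar in sequence, so the split between Cma2 and Mcpt4 is uncertain.

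Of 20 Glycolysis and hypoxia genes, 18 rose and 0 fell, 19 and 0 adjusted over the list alone (median 1.22, or 1.17 with bounds; adjusted p = 7.07e-13, and adjusted p = 0.0563 with an estimated correlation). Ankrd37 rose by 3.18 (SE 0.21, 1.14e-05), Egln3 by 2.68 (SE 0.16, 7.10e-06), and the aldolase gene Aldoc by 2.31 (SE 0.12, 4.02e-06). Probes of Egln3 differed here too, with 2.75 (adjusted p = 1.65e-05) and 0.23 (0.376) at the others in a limma fit of every probe. The Unfolded protein and amino acid response list had 11 of 23 up and 0 down, also adjusted over the list alone (median 0.41, adjusted p = 2.30e-04, and adjusted p = 0.132 with an estimated correlation), with Trib3 at 2.47 (SE 0.20, 4.42e-05). Hox genes and partners had 6 of 13 up and 0 down, 6 and 1 adjusted over the list alone (median 0.32, or 0.29 with bounds; adjusted p = 0.0079, and adjusted p = 0.132 with an estimated correlation), and missed the threshold among genes detected on all 9 arrays (adjusted p = 0.0740, the highest in a range from 6.56e-04).

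Of 16 Heat shock and handling stress genes, 1 rose and 11 fell, also adjusted over the list alone (median -1.02, adjusted p = 4.44e-05, and adjusted p = 0.217 with an estimated correlation). All 9 immediate early members fell, among them Fos by 3.31 (SE 0.19, 6.68e-06) and Zfp36 by 1.71 (SE 0.11, 1.13e-05). Mast cell and basophil genes had 3 of 23 up and 12 down, 4 and 13 adjusted over the list alone (median -0.67, or -0.60 with bounds; adjusted p = 0.0031, and adjusted p = 0.470 with an estimated correlation). In MN1-TEL replicate 2 the median of these genes differed by -0.49 from the other MN1-TEL arrays, against -0.39 to 0.32 on the 6 arrays of the other groups. Hpgds, a prostaglandin synthase of mast cells, fell by 3.42 (SE 0.28, 4.32e-05) and Cma1, a chymase, by 2.48 (SE 0.27, 1.94e-04). Monocyte and macrophage genes had 3 of 26 up and 11 down, 3 and 13 adjusted over the list alone (median -0.46, adjusted p = 0.0097, and adjusted p = 0.389 with an estimated correlation). Cholesterol synthesis genes had 0 of 17 up and 5 down, 0 and 8 adjusted over the list alone (median -0.39, adjusted p = 0.0140, and adjusted p = 0.217 with an estimated correlation), a call lost without del DBD replicate 1 (adjusted p = 0.0565, the highest in a range from 0.0017).

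The Mature neutrophil list did not pass the threshold between the 2 fusion constructs, with 4 of 27 up and 11 down, 4 and 12 adjusted over the list alone (median -0.34, adjusted p = 0.0718). It passed without del DBD replicate 3 (0.0329) and without a detection filter (0.0201), in a range of 0.0201 to 0.661. The p53 targets (0.0686), Cytokine receptors (0.0686) and Myeloid transcription factors (0.0701) also missed the threshold. They passed without MN1-TEL replicate 2 (0.0226, 0.0226 and 0.0329) or del DBD replicate 3 (0.0343, 0.0496 and 0.0325) and with the replicate number as a block (0.0467 each), and ranged from 0.0064 to 0.134, 0.0183 to 0.115 and 0.0325 to 0.124. Chil3, a chitinase-like protein, rose by 3.44 (SE 0.20, 6.92e-06) and the gelatinase gene Mmp9 was at least 4.01-fold lower (2.13e-04), detected on 2 of 3 del DBD arrays. Chil3 has a near-identical neighbour, Chil4, so its signal is uncertain. Primary granule genes had 5 of 12 up and 2 down, 6 and 2 adjusted over the list alone (adjusted p = 0.108), with Elane at 2.84 (SE 0.22, 3.42e-05) and Mpo at 2.70 (SE 0.18, 1.41e-05). Medians and means differed in sign for Dendritic cell and MHC class II (0.14 and -0.08), Erythroid (0.16 and -0.04), Cell cycle inhibitors (-0.03 and 0.19) and Inflammatory and NF-kB genes (0.0030 and -0.16). Cdkn2b rose by 1.48 (SE 0.26, 0.0027). Meis1 rose by 0.59 (SE 0.18, 0.0396), a call lost in 13 of 24 alternatives, with adjusted p from 0.0174 to 0.107. Among them were those that left out MN1 replicate 2 (0.0594), MN1-TEL replicate 2 (0.0794) or 3 (0.103), or del DBD replicate 1 (0.106), 2 (0.0772) or 3 (0.0977). Cd34 stood at 0.34 (SE 0.15, 0.126), passing without MN1-TEL replicate 1 (0.0233, the lowest in a range up to 0.367), and Cdkn2a at 0.15 (SE 0.57, 0.869). The 2-fold count was 408 without background correction, 539 with a normexp offset of 50 and 458 among genes detected on all 9 arrays. Without a detection filter 15 lists passed the threshold in place of 7, and without del DBD replicate 3 it was 11. Other divisions of the 6 arrays, which mix both groups on each side, gave up to 7.

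**Figure D4:**
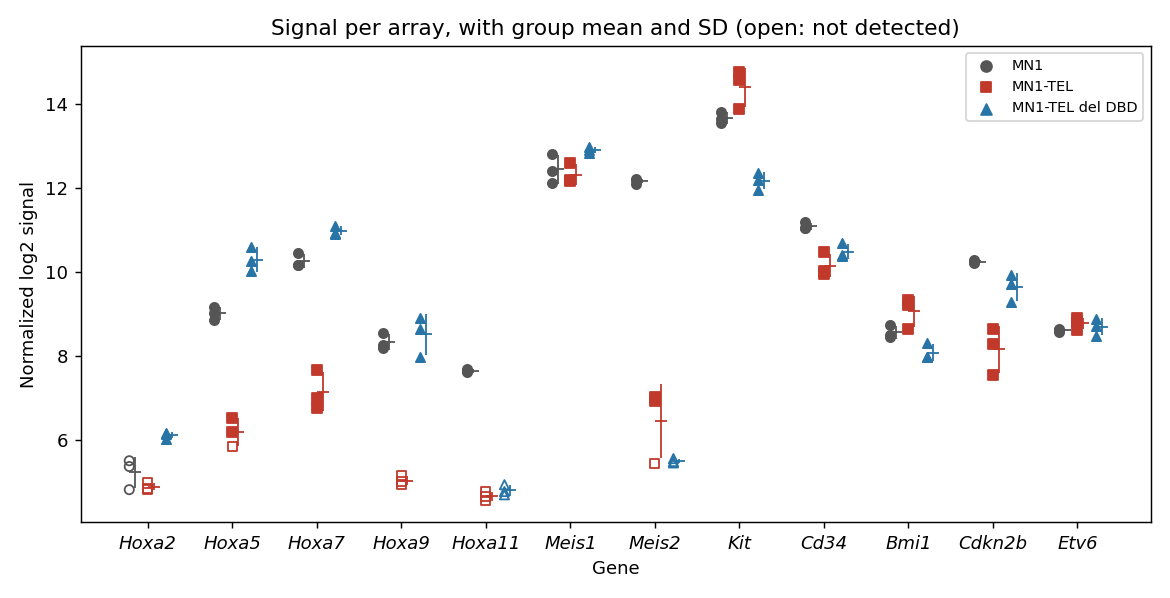
Normalized log2 signal (y axis) of 12 genes (x axis) on each array by construct, with group mean and SD, and open symbols where the probe was not detected. Hoxa9 is at background on the 3 MN1-TEL arrays, while Meis2 is bright on the 3 MN1 arrays and low in both fusion constructs.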

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

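Of the tests in this part, the test of single probes in the differences from MN1, the test on mast cell genes and the test for a mixture of cells were chosen after the result was seen.

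Probes without a gene name, which the comparisons of genes do not use, carried signal as well. Of 2064 such probes, 926 changed in MN1-TEL against MN1, 574 in del DBD against MN1 and 393 in del DBD against MN1-TEL (limma, adjusted p threshold of 0.05), or 44.9%, 27.8% and 19.04%. Among named probes the shares were 49.4%, 32.0% and 24.1%.

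Against MN1, 4995 genes changed in MN1-TEL and 3386 in del DBD, and the MN1 arrays were dimmer before normalization (mean raw intensity 667 against 943 and 875). A difference in brightness acts on a probe through its intensity, and a smooth trend on intensity accounted for at most 2.10% of the variance of the differences from MN1 before arrays were normalized to each other (bootstrap interval 1.44% to 2.72%). A uniform shift, which adds nothing to that share (median log2 differences 0.68 and 0.62), is removed by normalization. With cyclic loess, which removes shift and trend alike, 5011 and 3368 genes changed, 4677 and 3156 of them the same genes, which argues against shift and trend as the whole cause. Loss of signal at single probes, such as from degraded RNA, is argued against as the whole cause too, since at most 10.8% of the excess variance of the differences from MN1 belonged to 1 of 2 probes of a gene and not to both (8.93% to 13.1%), while differences in RNA or culture that move both probes of a gene, and the constructs themselves, stay open.

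Each set of 6 arrays has 10 divisions into 3 and 3, which are too few for a share under 0.05. The counts of changed genes, 4995 in MN1-TEL against MN1, 3386 in del DBD against MN1 and 2689 in del DBD against MN1-TEL, and of 2-fold changes, 1862, 1130 and 847, were each reached in 1 of the 10, the real one. The highest of the others was 0 for each (limma, adjusted). At an unadjusted p under 0.05 the real divisions gave 5502, 4251 and 3733 genes and the others up to 459, 147 and 862. For lists, the real counts of 14, 9 and 7 were reached in 2, 4 and 2 of the 10, and the highest of the others were 15, 10 and 7. In every division but the real one, each side holds arrays of both groups. Part of the real difference then stays between the sides and the rest enters the spread. Few gene calls were thus to be expected there, and lists called there can carry part of the real difference. Neither count shows what unchanged groups would give.

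Replicate 2 of MN1-TEL stood apart from the other MN1-TEL arrays. Over 3294 genes with more than 1 kept probe, 69.8% of that array's excess variance belonged to 1 of 2 probes and not to both (65.0% to 74.5%). A loss of signal at single probes, such as from degraded RNA, may account for this. The share was 10.8% for the difference between MN1-TEL and MN1, but that is a contrast between groups and not a single array. On the other arrays, deviations from the group correlated between the 2 probes at 0.18 to 0.43, against 0.31 on replicate 2. Between 9 and 50 of these genes were at least 2-fold lower on the other arrays, against 305 on replicate 2. Several lists moved in that array: Mast cell and basophil had a median of -0.49 with 17 of 23 genes lower, Primary granule lay at 0.36, ETS family at -0.31, and T and NK lymphoid and Retinoid pathway, with 5 measured genes each, at 0.56 and 0.49. MN1-TEL replicate 1 lay at 0.40 for the mast list and 0.36 for ETS family, against a reference that includes replicate 2. On the 6 arrays of the other groups the mast list ranged from -0.39 to 0.32, and 7 arrays are too few for a share under 0.05, so whether that culture held fewer mast cells stays open. Of the mast genes, 2 are also in the Stem and progenitor cells list, the brightest in MN1-TEL were Cpa3 at 14.97 and Cma1 at 14.70 (log2 means), and enrichment for c-kit would not remove mast cells.

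The del DBD arrays lay between MN1 and MN1-TEL on the first principal component, and 755 genes were significantly between the 2 groups. A mixture of MN1-like and MN1-TEL-like cells could place a culture there, but it cannot put a gene beyond both. At least 2-fold beyond both groups lay 169 genes, 89 above and 80 below, past the threshold in both comparisons, above a limit of 45.7, or 0.5% of genes, which argues against a mixture as the whole cause. A mixture for part of the genes, and an effect of the deleted domain, stay open.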

How the results depend on the processing

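No alternative reported here was added after the data were seen. Of 9113 values of named genes under the alternatives, 8815 kept direction and side of the threshold, 204 lost the threshold, 91 passed it and 3 reversed. For lists 1701 of 1776 kept both, 23 lost the threshold, 52 passed it and 0 reversed. The reversals were Mrgpra2b in MN1-TEL against MN1 at -0.18 among genes detected on all 9 arrays, where another probe stood for it, and, with every probe separately, Rbl1 at -0.77 and Gabpb1 at 1.08 in del DBD against MN1, where probes of the gene differ. Counts of 2-fold changes moved by over 1.5 times without background correction, to 1087, 606 and 408 in the order MN1-TEL against MN1, del DBD against MN1 and del DBD against MN1-TEL. They moved among genes detected on all 9 arrays, where fewer genes are tested, to 1115, 572 and 458, and with a normexp offset of 50 to 539 in the last. Without a detection filter 15 lists passed in del DBD against MN1-TEL. For these moves, other than that with fewer genes, the cause was not tested. An adjusted p threshold of 0.01 gave 2011 changed genes in del DBD against MN1, 1497 in del DBD against MN1-TEL and an overlap of 1597, as a stricter threshold must lower them. Leaving out each array in turn gave 4155 to 5426, 2293 to 4209 and 1880 to 3205 changed genes, 1737 to 1906, 1009 to 1142 and 753 to 875 with 2-fold changes, 13 to 15, 9 to 11 and 6 to 11 lists, and an overlap of 1795 to 3187. The 11 lists arose without del DBD replicate 3. The highest numbers of changed genes, 5426, 4209 and 3205, all arose without MN1-TEL replicate 2, which is not part of del DBD against MN1 but enters the shared spread. With the replicate number as a block the changed genes were 4777, 3097 and 2446 and the lists 14, 10 and 10, the gains being Stem and progenitor cells in del DBD against MN1 and p53 targets, Cytokine receptors and Myeloid transcription factors in del DBD against MN1-TEL. Deviations of arrays with the same number correlated between -0.16 and 0.18, and in 1 of 9 cases the best partner had the same number, so the numbers were not taken as pairs. The slide of each array is not given in the sources used here, and a block on it was not run, nor was a test on the authors' averaged table, which holds group means alone. Signal over background limits folds of dim genes, and 738, 576 and 388 genes were below background in 1 of the groups compared.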

Other observations

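The genes named in the next paragraph were chosen after their values were seen, while the test on neighbouring genes was chosen before its result was seen.

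Cells with del DBD also had genes that lay outside the range of both other groups, 301 above both and 258 below both at the adjusted threshold of limma. For each gene named here the 3 del DBD arrays did not overlap those of either other group. The carbonic anhydrase gene Car4, not detected in the other groups, was at least 5.30-fold higher than in MN1 and 5.73-fold higher than in MN1-TEL (adjusted p = 1.21e-06 and 3.78e-06), and the chitinase-like genes Chil3 (log2 differences 4.44 and 3.44) and Chil4 (5.05 and 3.39), which are near-identical and not separable here, were higher too. Adult beta globin genes Hbb-bs (3.08 and 2.73) and Hbb-bt (3.03 and 2.72), also near-identical, were higher in del DBD than in both, and the eosinophil-attracting chemokine gene Ccl24 was at least 2.98-fold and 3.22-fold higher. The Erythroid list names beta globin genes as Hbb-b1 and Hbb-b2, and Hbb-bs and Hbb-bt were not among its 10 measured genes of 28 listed. The measured genes did not rise with these globin genes as a list, which leaves the unmeasured members untested. Of its 10 genes, 2 rose and 4 fell against MN1 (camera adjusted p = 0.549). Against MN1-TEL 1 rose and 2 fell (0.896). Lower than in both were the heparan sulfate enzyme genes Hs6st2 (-3.26 and -4.54) and Hs3st1 (-2.74 and -3.17) and the adhesion gene Cadm1 (at least 9.60-fold and 8.60-fold, detected on 2 of 3 del DBD arrays). The ephrin receptor gene Epha3 was at least 21.05-fold and 4.35-fold lower, and Zfp521 at least 16.5-fold and 2.45-fold lower.

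Hoxa5, Hoxa7 and Hoxa9 lie in 1 cluster and were higher in del DBD than in MN1-TEL together, and a hypothesis is that genes that lie next to each other changed together more widely. Neighbours were tested genes that follow each other in gene order, 9107 pairs of 9129 genes. Untested genes may thus lie between them, and no limit on distance was set. Among neighbouring genes with different name stems, 56 pairs changed at least 2-fold in the same direction in del DBD against MN1-TEL, against a mean of 37.4 in 10000 permutations of gene order (one-sided permutation p = 0.0023, adjusted p = 0.0023). In MN1-TEL against MN1 there were 249 such pairs against 183, and in del DBD against MN1 119 against 69.5 (adjusted p = 1.2e-04 for each, from the smallest p the permutations can give). Duplicated genes with different names, whose probes may bind both copies, were not excluded by this test, so the 56 pairs do not show regulation of whole regions.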
